A study of Mus musculus with 8 samples.

How the data were processed

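Gene expression was measured by RNA sequencing in 8 libraries from mouse prostate, 2 each from Pten-deleted basal, CD1 basal, Pten-deleted luminal and CD1 luminal cells. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted from FACS-isolated cells with the RNeasy micro kit and libraries were prepared with the Ovation Solo RNA-seq system. The molecule is given as polyA RNA in the labels. The surface markers and gates of the sort, the sequencing batch, the animals behind each library and the strand setting of the counting are not given in the sources used here. Since nothing states that the 2 libraries of a group came from separate animals, p-values measure only the spread between these samples, which may be technical.

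FastQC, Trimmomatic, STAR 2.7.5a, Picard, HTSeq 0.11.1 and the build GRCm38 (mm10) are named in the submitters' processing notes. The deposited table held 1 signal value per gene and library, each being a gene's read count scaled by the authors to a total of 20000000 per library and rounded up to a whole number. The scaling was read from the column names and from the values themselves. The table had 49671 genes, of which 14293 were at 0 in every library and 101 symbols stood on more than 1 line. Of its gene identifiers 99.5% were found in GENCODE M21, which gave the coordinates on GRCm38. Because the scaled values of a library are multiples of the worth of 1 read, whole reads could be recovered. Between 99.61% and 99.97% of the values in a library came out as the rounded-up value of a whole number of reads, where 6.3% to 56.9% would by chance. For the 2 Pten-deleted luminal libraries and CD1 luminal replicate 2 the steps are wide enough that ordinary rounding gives the same reads. For the other libraries the recovery relies on the values having been rounded up. The worth of 1 read ran from 1.76 in Pten-deleted basal replicate 1 to 15.67 in Pten-deleted luminal replicate 1, and 3 reads, taken as the floor of a gene at 0, from 5.27 to 47.02.

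Libraries were scaled by the median ratio over the 16866 genes seen in all of them, with factors from 0.88 to 1.09, and log2(value + 10) was analysed with limma 3.58.1 in R 4.3.3. Genes with a value of at least 20 in at least 2 libraries were tested, 20733 in all. All 8 libraries entered 1 fit with 4 group means (lmFit, contrasts.fit and eBayes with a mean-variance trend), which left 4 residual degrees of freedom and gave a prior of 6.6. The comparisons were Pten-deleted against CD1 in basal cells and in luminal cells, luminal against basal in CD1 and after deletion, and the difference between the 2 Pten effects. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. A count test was the plan for a table of whole counts. As the values proved to be scaled, limma was used, as foreseen, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads were alternatives. Where a group held 1 to 3 reads of a gene, a ratio is given with its exact 95% counting interval. It compares the reads pooled over each group, per pooled and scaled depth, and can differ from the ratio of the mean levels. Where a group held 0 reads the fold is a bound computed against 3 reads in each of its libraries. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

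The design, the gene lists and the rule for naming genes were fixed before the data were examined. The rule took Pten in every library, and the 8 largest rises and 8 largest falls for each Pten comparison or 5 and 5 for each other comparison. It drew on genes past the threshold with separated libraries and a mean of at least 200, passing over predicted genes. For each list it took up to 4 members. The text gives those of these genes that carry each comparison. The genes plotted in the lineage and immune panels and Krt5 in basal cells were chosen after their values were seen. The 24 lists held 379 genes, 353 of them tested. They covered basal epithelial markers, luminal epithelial markers, prostatic secretion genes, proximal luminal progenitor markers, NF-kB target genes, innate sensors and their adaptors, interferon-stimulated genes, MHC class I and class II presentation, antimicrobial, acute phase and complement genes, cell cycle genes, p53 and senescence genes, FOXO target genes, sterol and fatty acid synthesis, glycolysis genes, EMT transcription factors and mesenchymal genes, and mitochondrially encoded genes. Markers of fibroblasts, smooth muscle, endothelium, leukocytes, neuroendocrine cells, and seminal vesicle and urothelium and a list of immediate early genes were included as signs of other cells or of dissociation. Lists were tested with camera at a preset correlation of 0.01 and again with the correlation estimated, and with fry, adjusted over the 24 lists.

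Replicates were compared before they were averaged. Their Pearson correlation across genes on the log2 scale was 0.991 in Pten-deleted basal, 0.971 in CD1 basal, 0.918 in Pten-deleted luminal and 0.965 in CD1 luminal cells, and in each group they differed by more than counting noise (chi-square per degree of freedom 3.38, 22.1, 7.14 and 8.01). The steps were tested on simulated data in which 100 genes were changed by log2 1 and 100 by log2 2. In the basal Pten comparison limma recovered 11% and 69% of these among 20862 genes tested, with 1.2% false calls. For luminal cells it recovered 17% and 85% among 20931 genes, with 12.8% false calls. For the lineage difference it recovered 17% and 71% among 20746 genes in CD1 mice, with 2.2% false calls, and 19% and 76% among 20808 genes after deletion, with 8.7% false calls. edgeR on simulated reads recovered 52% and 97% among 18831 genes in the basal comparison, with 17.7% false calls, and 25% and 89% among 18911 in the luminal one, with 6.6%. For the lineage difference its false calls were 7.3% in CD1 mice, among 18870 genes, and 2.6% after deletion, among 19149. Each comparison was simulated 1 time, with the same spread of a gene in every group. In the data the spread differed, the median absolute log2 difference between replicates being 0.16 in Pten-deleted basal and 0.45 in Pten-deleted luminal cells. The shares of false calls may therefore not hold for the real libraries. camera found the raised list and called 0 of 20 unchanged lists in a simulation that drew every gene independently. Correlation between the genes of a list was left out there, so its false calls for correlated lists are not known. Alternatives to the scaling, pseudocount, filter, trend, test, fold threshold and set of libraries were run, as were a replicate block and each library left out in turn. Thinning to one depth, library weights and leaving out the 2 libraries that stood apart (CD1 basal replicate 1 and Pten-deleted luminal replicate 1) were added after the values were seen. In groups of 2, which library is the atypical one cannot be told. Pten-deleted luminal replicates 1 and 2 correlated with the libraries of other groups at 0.839 to 0.896 and 0.839 to 0.897. No comparison was made of other splits of the samples, because groups of 2 allow too few. Near-identical gene copies, overlapping genes and antisense genes can share reads in these counts.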

Results

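Basal cells form the outer layer of the prostate epithelium, next to the stroma, whereas luminal cells face the duct lumen and produce the secretions of the gland. To ask how loss of the tumour suppressor Pten in basal cells changes cell fate, the study sequenced RNA from both cell types after sorting them from mouse prostates. The 8 libraries fell into 4 groups of 2, namely basal and luminal cells of CD1 mice (an outbred stock, used as controls) and basal and luminal cells taken 5 weeks after Pten deletion. The genotype given for the samples (K5CreER/Ptenfl/fl/RosaYFP) joins a Cre recombinase driven by the keratin 5 promoter, which is active in basal cells, with loxP-flanked Pten and a YFP reporter. It is written for the CD1 samples as well. Whether these came from CD1 wild-type mice or from uninduced mice of that genotype is therefore open. If they were CD1 wild-type mice, mouse stock and deletion cannot be separated, and differences called Pten effects here would include both. The labels used here do not say whether luminal cells were selected by the YFP reporter. The Pten-deleted luminal libraries can therefore hold luminal cells derived from deleted basal cells, luminal cells that kept Pten, or both. Depth differed between the groups. The 2 Pten-deleted basal libraries held 11388586 and 9652611 reads assigned to genes, and the 2 CD1 basal libraries 8396943 and 9292910. Pten-deleted luminal cells had 1276100 and 1707022, and CD1 luminal cells 3977082 and 2752098. At least 10 reads were seen for 18890 and 18432 genes in Pten-deleted basal cells, 18145 and 16866 in CD1 basal cells, 10226 and 11420 in Pten-deleted luminal cells and 14283 and 12734 in CD1 luminal cells. Loci of 18S and 45S ribosomal RNA took 22.22% and 15.34% of the reads in Pten-deleted luminal cells, 9.92% and 12.26% in CD1 luminal cells and between 2.79% and 3.48% in the 4 basal libraries. Levels are given as normalised reads, scaled to 20000000 per library, as the mean ± SD of the 2 libraries of a group. Fold changes were taken on the log2(level + 10) scale, which understates the change of weakly expressed genes.

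Pten itself (ENSMUSG00000013663, chromosome 19, 32757497 to 32826160 in GRCm38) was measured lower in both Pten-deleted groups than in their controls, and whether the basal fall passed depended on the test. Its level was 2670 and 2480 in Pten-deleted basal cells, 3880 and 4480 in CD1 basal cells, 2790 and 2720 in Pten-deleted luminal cells and 3140 and 3370 in CD1 luminal cells. The log2 fold change was -0.69 in basal cells (SE 0.16, limma adjusted p = 0.137) and -0.24 in luminal cells (SE 0.16, adjusted p = 0.333), and the difference between these effects was 0.45 (adjusted p = 0.259). The basal fall passed with DESeq2 (log2 -0.69, adjusted p = 0.0346) and with library weights in limma (adjusted p = 0.0183), and did not with edgeR (log2 -0.67, adjusted p = 0.0933). The value counts reads over the whole gene. Reads from exons that the deletion leaves in place, and from cells that kept the gene, are included, so that it checks the labels only in part.

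The first comparison asked what Pten deletion changed in basal cells. Leukocyte markers and prostatic secretion genes lay higher as groups, while few genes passed as lower, among them Spry4, Socs2 and Cish. Of 20733 genes tested, 91 rose and 10 fell (limma), each by at least 2-fold. At an unadjusted p under 0.05, 893 lay higher and 492 lower. Among the genes with the largest rise was Lyz2, the lysozyme of macrophages and neutrophils (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321), at 484 ± 76.6 in Pten-deleted and 2.45 ± 3.47 in CD1 basal cells. With 2 reads in the CD1 libraries together, the ratio was 220 (95% counting interval 60.6 to 1820), and the log2 fold change was 5.33 (SE 0.38, limma adjusted p = 0.000218). Mmp12, the macrophage elastase, stood at 213 ± 19.2 with 2 reads in CD1 basal cells (ratio 96.9, 26.5 to 805, adjusted p = 0.00967). Lilrb4a, an inhibitory receptor of myeloid cells, stood at 219 ± 5.54 with 3 reads (ratio 66.7, 22.6 to 326, adjusted p = 0.00145). Cd74, the invariant chain of MHC class II, rose 8.34-fold from 41.9 ± 2.33 to 422 ± 29.9 (log2 3.06, SE 0.27, adjusted p = 0.00115). A further 3 of the largest rises were genes that CD1 luminal cells expressed more strongly than CD1 basal cells. Pnliprp1, a pancreatic lipase-related protein, rose 19-fold to 463 ± 115 (744 ± 90.9 in CD1 luminal cells, adjusted p = 0.000218). Ms4a5 rose 12-fold to 517 ± 86.3 (adjusted p = 0.00906) and Ren1, the renin gene, 8.57-fold to 2310 ± 188 (adjusted p = 0.0213). Lyz2 and Ren1 can share reads with near-identical copies, so their values are uncertain. Among the genes that fell, Spry4, an inhibitor of receptor tyrosine kinase signalling to ERK, dropped from 4760 ± 112 to 1470 ± 117 (log2 -1.69, SE 0.2, adjusted p = 0.00656). The cytokine signalling suppressors Socs2 (1580 ± 78.5 to 586 ± 45.3, adjusted p = 0.0184) and Cish (3700 ± 158 to 1730 ± 132, adjusted p = 0.0392) and the cyclin D1 gene Ccnd1 (log2 -1.4, adjusted p = 0.0428) fell as well.

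Leukocyte markers lay higher as a group in Pten-deleted basal cells. All 14 tested lay above CD1 basal cells, with a median log2 fold change of 1.65 (camera adjusted p = 2.15e-12, adjusted p = 0.0398 with an estimated correlation), and 2 passed the test singly, Lyz2 and Laptm5. Adjusted over the list alone, 8 rose. Of 7 MHC class II genes 2 rose (3 adjusted over the list alone), Cd74 and H2-Aa (173 against 12.6, limma adjusted p = 0.0141), with a median of 1.59 (camera adjusted p = 9.75e-06, adjusted p = 0.109 with an estimated correlation). All 11 fibroblast markers likewise lay higher, with a median of 1.39 (camera adjusted p = 2.07e-14, adjusted p = 0.213 with an estimated correlation). The proteoglycan gene Lum (29.5 to 173, limma adjusted p = 0.0185) and the matrix gene Fbln1 (142 to 550, adjusted p = 0.0325) passed, and 9 did so adjusted over the list alone. Il1b, encoding interleukin-1β, was the member of 25 NF-kB target genes that rose (5.8 to 93.2, adjusted p = 0.0319). Adjusted over the list alone 5 were higher and 1 lower, with a median of -0.01 beside a mean of 0.37 (camera adjusted p = 0.711). Of 16 antimicrobial, acute phase and complement genes 1 rose (1 adjusted over the list alone), the immunoglobulin receptor Pigr (272 to 1620, limma adjusted p = 0.0199). The median of that list was 0.32, or 0.3 with members at 0 set to their bound (camera adjusted p = 0.00674, adjusted p = 0.658 with an estimated correlation).

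Genes of the luminal lineage lay higher in Pten-deleted than in CD1 basal cells, and basal markers shifted little. Prostatic secretion genes had a median log2 fold change of 0.74 over 13 members (camera adjusted p = 2.66e-08, adjusted p = 0.0398 with an estimated correlation). The transglutaminase Tgm4 passed singly, rising from 10100 ± 2280 to 28000 ± 1120 (limma adjusted p = 0.0392), and 6 members rose adjusted over the list alone. Of 16 luminal markers the prolactin receptor Prlr (214 ± 10.2 to 728 ± 56.8, adjusted p = 0.00239) and Dpp4 (51.2 to 207, adjusted p = 0.0314) rose. Adjusted over the list alone 4 rose, and the median was 0.28 (camera adjusted p = 0.000182, adjusted p = 0.36 with an estimated correlation). Without CD1 basal replicate 1 this median was 0.02 and its call was lost, and without CD1 basal replicate 2 it was 0.5. Of 15 markers of proximal luminal progenitors 2 rose, Clu (473 ± 6.03 to 1900 ± 459, limma adjusted p = 0.0435) and Prom1 (254 to 650, adjusted p = 0.0194), and 3 adjusted over the list alone. Their median was 0.84 (camera adjusted p = 1.91e-05, adjusted p = 0.509 with an estimated correlation). Lgals7, a galectin of stratified epithelia, was the 1 basal marker of 18 that rose (145 to 786, limma adjusted p = 0.0338, 1 adjusted over the list alone). The median of the list was -0.01 beside a mean of 0.24 (camera adjusted p = 0.305). Krt5 stood at 13900 ± 449 in Pten-deleted and 9530 ± 3220 in CD1 basal cells and did not pass.

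No member passed singly in the remaining 15 lists, which held 218 tested genes (limma). At an unadjusted p under 0.05, 20 of these lay higher and 12 lower, edgeR called 6 higher and 2 lower, and DESeq2 7 and 3. The camera test passed 3 of these lists as groups. They were the EMT transcription factors and mesenchymal genes (median 0.22, camera adjusted p = 0.000231, adjusted p = 0.509 with an estimated correlation, 3 risen adjusted over the list alone) and the seminal vesicle and urothelial markers (0.87, adjusted p = 0.0241, adjusted p = 0.509 with an estimated correlation, 1 risen adjusted over the list alone). The interferon-stimulated genes were the other (0.36, camera adjusted p = 0.0494, adjusted p = 0.712 with an estimated correlation, 1 risen adjusted over the list alone). These medians depended on single libraries. Without CD1 basal replicate 1 or 2 the EMT median was 0.45 or 0.66. The seminal vesicle median was 0.16 and 1.45 without Pten-deleted basal replicate 1 or 2, and 0.36 with its call lost without CD1 basal replicate 2. For the interferon-stimulated genes the call was lost without any 1 library except Pten-deleted basal replicate 1, and the median was -0.01 without Pten-deleted basal replicate 2. Medians of the other groups that did not pass were 0.21 for innate sensors, -0.04 for MHC class I, 0.33 for cell cycle genes, and 0.13 for p53 and senescence genes (mean -0.11). They were -0.05 for sterol and fatty acid synthesis (mean 0.01), 0.02 for glycolysis, -0.03 for smooth muscle markers (mean 0.01), 0.41 for neuroendocrine markers and 0 for mitochondrially encoded genes (mean -0.09). FOXO target genes had a median of -0.21, which passed at -0.41 without CD1 basal replicate 1. The endothelial median was 0.17 but passed at -0.51 and 0.75 without CD1 basal replicate 1 or 2, and that of immediate early genes was -0.06 but passed at -0.42 and 0.33 without the same libraries.

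The number of basal calls rested on each of the 4 basal libraries. Leaving out 1 of them leaves a group of 1, with the spread taken from the other groups, so that a loss of calls is partly built in. Without Pten-deleted basal replicate 1 or 2, or CD1 basal replicate 1 or 2, the test called 13, 12, 13 and 7 genes as higher and none as lower, where 153, 145, 467 and 719 lay lower at an unadjusted p under 0.05. It called 158 and 148 as higher and 25 and 25 as lower without Pten-deleted luminal replicate 1 or 2, and 57 as higher without CD1 luminal replicate 2. With either CD1 luminal library left out 5 were lower. Of the 23 genes named above as changed in basal cells, Lyz2, Pnliprp1, Lilrb4a and Cd74 kept their call without each library. The other 19 lost it without at least 1 of them, although no log2 fold change left 0.74 to 1.25 times its value. After thinning to 1276100 reads limma called no member of the basal marker, secretion, progenitor, NF-kB and fibroblast lists, where 27 of their 82 genes were higher and 1 lower at an unadjusted p under 0.05. edgeR called 249 genes as higher and 54 as lower. In 1 simulated data set for this comparison 17.7% of its calls were false, against 1.2% of those by limma. That simulation gave a gene the same spread in every group, unlike the data, so these shares may not hold here.

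**Figure D1:**
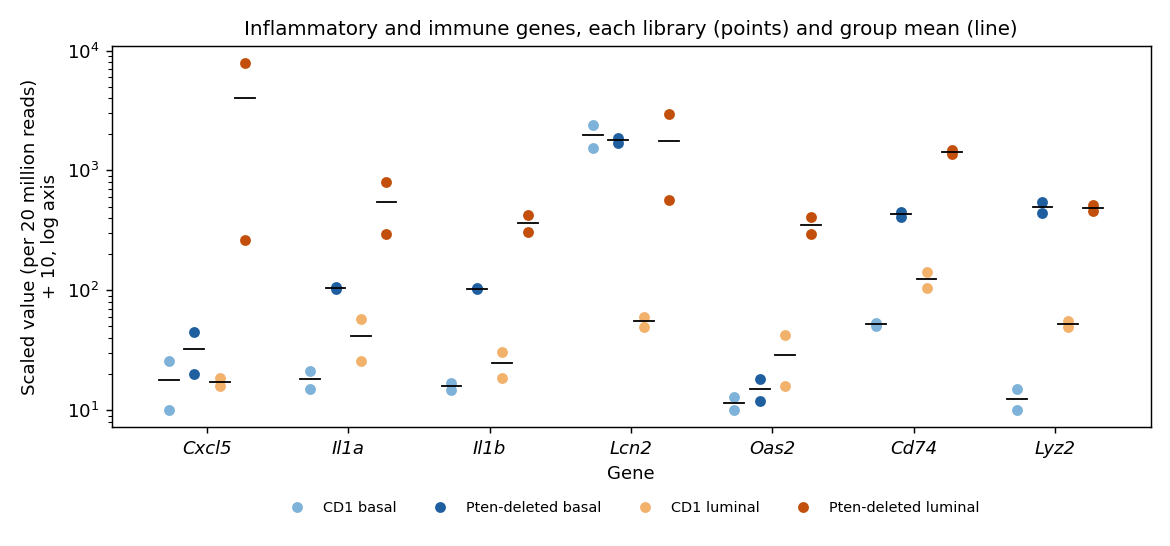
Normalised reads (of 20000000) plus 10, on a log axis, of Cxcl5, Il1a, Il1b, Lcn2, Oas2, Cd74 and Lyz2 in each of the 8 libraries, with points for libraries and lines for group means. Cxcl5 stood at 251 and 7830 in the Pten-deleted luminal libraries, and Cd74 at 401 and 443 in Pten-deleted and 43.5 and 40.2 in CD1 basal cells.

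The second comparison asked what differed in luminal cells after Pten deletion. Of 18 basal epithelial markers 17 rose, as did 17 of 25 NF-kB targets, 16 of 30 interferon-stimulated genes and 11 of 20 cell cycle genes, while 6 of 13 prostatic secretion genes fell. With every library thinned to 1276100 reads these counts were 14, 15, 9, 5 and 3, in the same order. The camera test passed 15 of the 24 lists, and 0 with an estimated correlation. In all 2082 genes rose and 1245 fell (limma), 62.6% of the calls being higher, or 52.4% with the values as deposited. The largest rises included Selp, the adhesion molecule P-selectin, at 4000 ± 2390 against 9.71 ± 1.59 with 3 reads in CD1 luminal cells (ratio 406, 138 to 1980, limma adjusted p = 0.000262). The hormone gene Stc1 (ratio 95.5, 25.6 to 803, adjusted p = 0.000329), the interleukin-1 receptor antagonist Il1rn (ratio 214, 58.4 to 1780, adjusted p = 0.00142) and Tnip3 (46.9-fold, adjusted p = 0.000747), whose product binds the NF-kB inhibitor A20, were also among them. Cxcl5, a chemokine that attracts neutrophils (ENSMUSG00000029371, chromosome 5, 90759360 to 90761624), was measured at 251 and 7830 in Pten-deleted and at 5.91 and 8.59, or 2 reads, in CD1 luminal cells (ratio 780, 215 to 6450, log2 6.38, SE 1.21, adjusted p = 0.00694). Ltf, encoding lactoferrin, rose 164-fold (log2 7.36, SE 1.24, adjusted p = 0.00407), at 1500 and 6320 in the 2 Pten-deleted libraries. Leaving out Pten-deleted luminal replicate 2 lowered the log2 fold change of Cxcl5 to 3.91, and its call was lost without CD1 luminal replicate 1 (6.26) or 2 (6.48), as was that of Ltf without CD1 luminal replicate 2 (6.42). Spdef, a transcription factor of secretory epithelium (818 ± 90.9 to 147 ± 55.1, log2 -2.44, SE 0.38, adjusted p = 0.00284), Gucy2g (log2 -2.5, adjusted p = 0.00362) and Cercam (log2 -2.44, adjusted p = 0.00391) were among the largest falls.

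Basal markers rose together in Pten-deleted luminal cells. Of 18 tested 17 rose (18 adjusted over the list alone), with a median log2 fold change of 1.85 (camera adjusted p = 4.86e-17, adjusted p = 0.134 with an estimated correlation). Keratin 5 (Krt5, ENSMUSG00000061527, chromosome 15, 101707070 to 101712898) rose 12.7-fold from 157 ± 66.8 to 2040 ± 348 (log2 3.67, SE 0.29, limma adjusted p = 9.81e-05). Krt17 rose 12.4-fold from 579 ± 387 to 6600 ± 1950 (adjusted p = 0.000385) and the hemidesmosome collagen Col17a1 10.1-fold from 220 ± 89.1 to 2240 ± 440 (adjusted p = 9.15e-05). These levels stayed below those of CD1 basal cells, where Krt5 was 9530 ± 3220. Of 13 prostatic secretion genes 6 fell (8 adjusted over the list alone), with a median of -1.14 (camera adjusted p = 6.38e-05, adjusted p = 0.134 with an estimated correlation). Tgm4 fell from 263000 ± 73400 to 86200 ± 4190 (adjusted p = 0.00371) and probasin, Pbsn, from 119000 ± 39400 to 50200 ± 22000 (log2 -1.28, adjusted p = 0.0201). The 16 luminal markers split, with 5 fallen and 1 risen (6 and 3 adjusted over the list alone), and their median of 0.13 differed in sign from their mean of -0.25 and from the camera test (adjusted p = 0.401). Among the fallen were Spdef and the homeobox gene Nkx3-1 (8090 ± 1620 to 2730 ± 545, log2 -1.56, adjusted p = 0.00712). The call of Nkx3-1 was lost without CD1 luminal replicate 2 (-1.39), and that of Pbsn without CD1 luminal replicate 2 (-0.96) or Pten-deleted luminal replicate 2 (-0.83). Progenitor markers rose in 12 of 15 cases (14 higher and 1 lower adjusted over the list alone), with a median of 3.17, or 2.04 without Pten-deleted luminal replicate 2 (camera adjusted p = 1.43e-09, adjusted p = 0.188 with an estimated correlation). They included Ly6d (13.5 ± 3.72 to 999 ± 1010, adjusted p = 0.00115), Wfdc2 (120 to 3010, adjusted p = 0.00189) and Clu (1590 ± 563 to 17600 ± 9590, adjusted p = 0.000358).

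**Figure D2:**
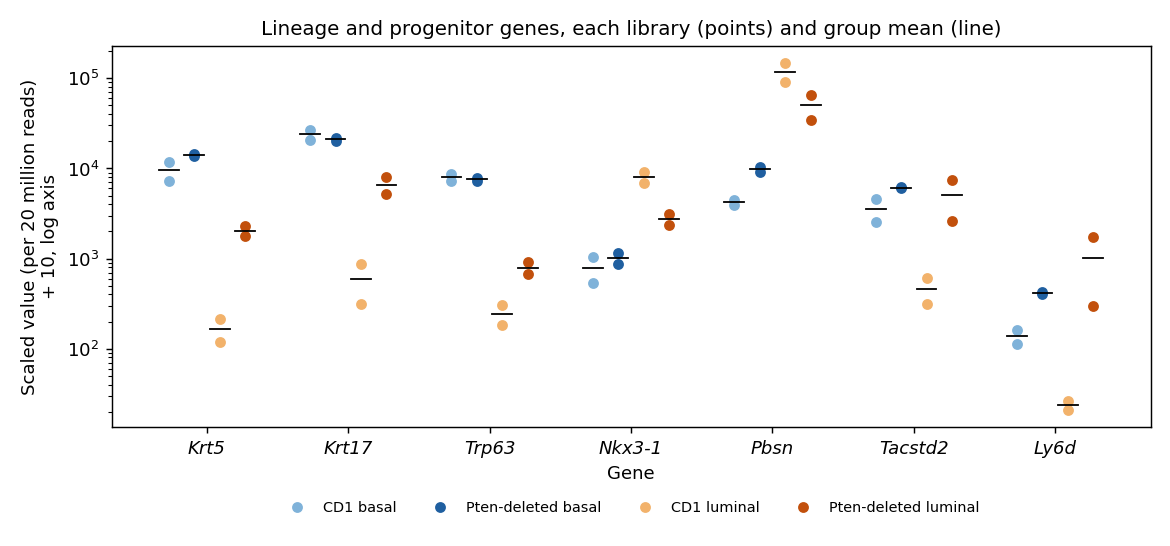
Normalised reads (of 20000000) plus 10, on a log axis, of Krt5, Krt17, Trp63, Nkx3-1, Pbsn, Tacstd2 and Ly6d in each of the 8 libraries, with points for libraries and lines for group means. Krt5 stood at 1790 and 2280 in Pten-deleted luminal cells, between the CD1 luminal values of 204 and 109 and the CD1 basal values of 7250 and 11800.

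Immune lists were looked at in the same luminal comparison. Of 25 NF-kB target genes 17 rose (18 adjusted over the list alone) and none fell, with a median of 1.33 (camera adjusted p = 5.37e-10, adjusted p = 0.182 with an estimated correlation). The cytokine genes Il1b (14.6 ± 8.56 to 355 ± 80.4, limma adjusted p = 0.000642) and Il1a (31.5 to 540, adjusted p = 0.00268) rose 15.1-fold and 12.7-fold, beside means of 93.2 and 93.6 in Pten-deleted basal cells. Their effects were not shown to differ between the cell types (interaction adjusted p = 0.292 and 0.443). All 30 interferon-stimulated genes lay higher and 16 rose (23 adjusted over the list alone), with a median of 1.63 (camera adjusted p = 1.98e-11, adjusted p = 0.167 with an estimated correlation). Ifit3 went from 41.2 ± 12.8 to 1060 ± 588 (adjusted p = 0.000594) and Oas2, a sensor of double-stranded RNA, from 19.1 ± 18.6 to 342 ± 78.1 (adjusted p = 0.00245). Of 22 innate sensors and adaptors 7 rose (7 higher and 4 lower adjusted over the list alone), among them the inflammasome sensor Nlrp3 (ratio 41.1, 6.44 to 1720, adjusted p = 0.00294) and the lipopolysaccharide co-receptor Cd14 (133 to 1080, log2 2.67, adjusted p = 0.00762). The median was 0.49 (camera adjusted p = 0.00417, adjusted p = 0.182 with an estimated correlation). Of 13 MHC class I genes 4 rose (8 adjusted over the list alone), with a median of 1.04 (camera adjusted p = 4.47e-05, adjusted p = 0.188 with an estimated correlation). Among them were H2-K1 (3030 to 7320, adjusted p = 0.00164) and H2-D1 (4360 to 9920, adjusted p = 0.00213). MHC class II genes rose in 4 of 7 cases (4 adjusted over the list alone), with Cd74 11.6-fold higher at 1410 ± 72.9 (adjusted p = 9.81e-05) and a median of 2.21 (camera adjusted p = 0.00397, adjusted p = 0.167 with an estimated correlation). Of 16 antimicrobial, acute phase and complement genes 5 rose (5 adjusted over the list alone), such as the siderophore-binding Lcn2 (45 ± 7.45 to 1740 ± 1680, adjusted p = 0.000959). Their median was 1.06, or 0.66 with members at 0 set to their bound (camera adjusted p = 0.000249, adjusted p = 0.302 with an estimated correlation). Lcn2 stood at 1770 in Pten-deleted basal cells, where it had not risen over CD1 basal cells (log2 -0.12, not passed). The Oas, Ifit and H2 genes have near-identical relatives with which they can share reads, so their single values are uncertain.

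Part of the immune groups depended on Pten-deleted luminal replicate 2. Without it the calls of innate sensors (median 0.51), MHC class II (1.76) and antimicrobial genes (0.33) were lost, the MHC class I median was 0.47 and the log2 fold change of Cd14 was 1.7. The call of Cd14 was lost without CD1 luminal replicate 2 (2.33). Leukocyte markers moved with the immune groups, with 5 of 14 risen (6 adjusted over the list alone) and a median of 1.3 (camera adjusted p = 0.000249, adjusted p = 0.134 with an estimated correlation). Ptprc, the common leukocyte antigen CD45, had 1 read in CD1 luminal cells (ratio 67.7, 11.2 to 2770, limma adjusted p = 0.000608), and Lyz2 was 9.32-fold higher (adjusted p = 0.000697). Endothelial markers rose in 6 of 10 cases (7 adjusted over the list alone), with a median of 2.31 (camera adjusted p = 1.57e-06, adjusted p = 0.188 with an estimated correlation). Examples were Vwf, the von Willebrand factor (24.5 ± 22.5 to 931 ± 456, adjusted p = 0.00118), and Cdh5, the endothelial cadherin (18.4 ± 3.25 to 813 ± 447, adjusted p = 0.0023). Smooth muscle markers rose in 7 of 9 cases (8 adjusted over the list alone), with a median of 1.31 (camera adjusted p = 1.57e-06, adjusted p = 0.167 with an estimated correlation). Myh11, a smooth muscle myosin, went from 198 ± 97 to 1630 ± 385 (adjusted p = 0.000477) and Acta2 from 223 to 929 (adjusted p = 0.000705). None of the 11 fibroblast markers passed in luminal cells (limma, median -0.41, camera adjusted p = 0.152), and at an unadjusted p under 0.05 none was higher and 2 were lower, with 1 lower by edgeR and 2 by DESeq2. Without CD1 luminal replicate 1 their median was -0.94 and passed.

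Lists of proliferation and metabolism followed in Pten-deleted luminal cells. Of 20 cell cycle genes 11 rose (14 adjusted over the list alone), with a median of 1.34 (camera adjusted p = 1.09e-08, adjusted p = 0.134 with an estimated correlation). Mki67, the proliferation marker, went from 362 ± 246 to 2230 ± 122 (limma adjusted p = 0.00153) and the replication licensing gene Mcm3 from 22 ± 19 to 327 ± 82 (adjusted p = 0.00116), beside 296 and 141 in Pten-deleted basal cells. Sterol and fatty acid synthesis genes rose in 7 of 17 cases (9 adjusted over the list alone), with a median of 0.52 (camera adjusted p = 1.9e-05, adjusted p = 0.134 with an estimated correlation). They included Hmgcs1 (576 ± 62.5 to 2020 ± 344, adjusted p = 0.000459) and Elovl6 (35.1 to 318, adjusted p = 0.000436). Of 16 glycolysis genes 6 rose (7 adjusted over the list alone), among them Pfkfb3 (324 to 1310, adjusted p = 0.00167), with a median of 0.57, or 0.25 without Pten-deleted luminal replicate 2 (camera adjusted p = 0.000138, adjusted p = 0.297 with an estimated correlation). Of 13 p53 and senescence genes 1 rose and 1 fell (1 and 1 adjusted over the list alone), with a median of 0.38 (camera adjusted p = 0.19). The cell cycle inhibitor Cdkn1a rose from 913 ± 55.2 to 3100 ± 136 (adjusted p = 0.000227), and Glb1, the lysosomal β-galactosidase, fell from 991 to 394 (adjusted p = 0.00598), a call lost without CD1 luminal replicate 1 (-1.14). Of 16 FOXO target genes 4 rose (5 adjusted over the list alone), such as the kinase gene Pdk4 (176 to 1140, adjusted p = 0.00104), with a median of 0.16 (camera adjusted p = 0.0864). Pdk4 was higher still in Pten-deleted basal cells, at 5270, where it had not risen over CD1 basal cells (log2 -0.75, not passed). Of 13 mitochondrially encoded genes 4 rose (4 adjusted over the list alone), with a median of 0.03 beside a mean of 0.66 (camera adjusted p = 0.108), including mt-Co2 (88.2 to 415, log2 2.25, adjusted p = 0.0113), which was lost without CD1 luminal replicate 2 (1.58). After thinning to 1276100 reads 0 of the 13 passed (limma), with 4 higher at an unadjusted p under 0.05, whereas edgeR and DESeq2 on all reads each called 4.

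Few members of the other lists changed in luminal cells. Snai2 (69.9 to 318, limma adjusted p = 0.00424) was the 1 of 15 EMT genes that rose (1 adjusted over the list alone), with a median of 0.16 (camera adjusted p = 0.251), which passed at 0.51 without CD1 luminal replicate 2. Of 4 neuroendocrine markers 2 rose (2 adjusted over the list alone), at a median of 1.11, or 0.56 with members at 0 set to their bound (camera adjusted p = 0.148). Neither of these calls was made by edgeR or DESeq2, which called 0, or by limma after thinning to 1276100 reads, where 1 member was higher at an unadjusted p under 0.05. Of 14 immediate early genes Socs3 rose (log2 0.92, adjusted p = 0.0218, 1 adjusted over the list alone), the median being 0.24 (camera adjusted p = 0.351) and passing at 0.34 without CD1 luminal replicate 2. The call of Socs3 was lost without CD1 luminal replicate 1 (0.55) or Pten-deleted luminal replicate 2 (0.86). The 6 seminal vesicle and urothelial markers had a median of -1.71, or -1.66 with members at 0 set to their bound, and -3.22 without CD1 luminal replicate 2, where it passed (camera adjusted p = 0.0876 with all libraries). None passed singly (limma), 1 fell adjusted over the list alone, 2 were lower at an unadjusted p under 0.05, and edgeR and DESeq2 each called 1 lower. The number of luminal calls depended on the estimate of the spread, which was shared with the basal libraries. With only the 4 luminal libraries in the fit 3 genes were higher and none lower, against 1484 and 756 by edgeR. It was 773 and 165 without CD1 luminal replicate 2 and 1195 and 368 without CD1 luminal replicate 1. The lower calls numbered 611 and 609 without Pten-deleted basal replicate 1 or 2, and 1878 without Pten-deleted luminal replicate 2.

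**Figure D3:**
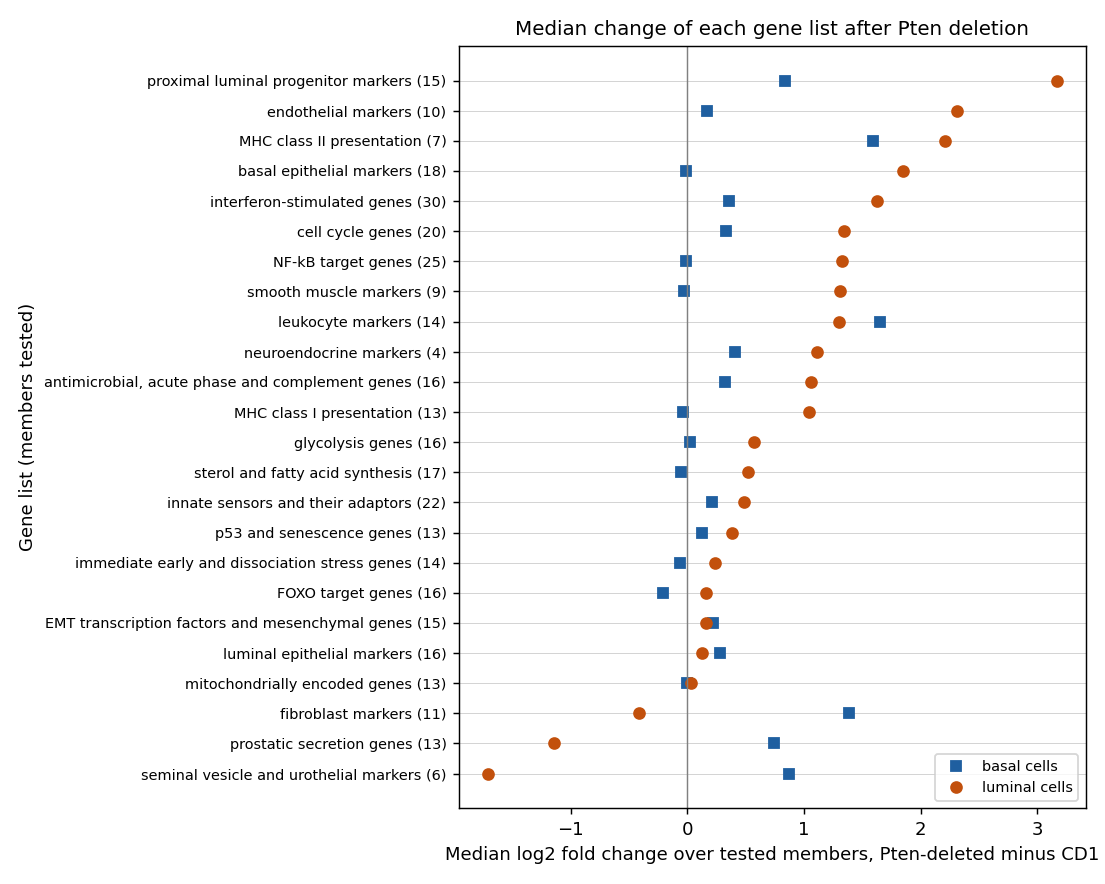
Median log2 fold change of each of the 24 gene lists after Pten deletion, with squares for basal and circles for luminal cells. The median of the basal epithelial markers was -0.01 in basal and 1.85 in luminal cells, and that of the leukocyte markers 1.65 and 1.3.

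The lineage difference in CD1 mice served as a reference for these shifts. Basal and luminal cells differed at 3446 genes higher in luminal and 3969 higher in basal cells (limma), and both sorted groups carried the markers of their names. Of 18 basal markers 16 were lower in luminal cells (median log2 -4.2, camera adjusted p = 3.28e-15, adjusted p = 0.247 with an estimated correlation), with Krt5 58.1-fold lower (limma adjusted p = 3.27e-07). Of 13 secretion genes 12 were higher (median 4.72, camera adjusted p = 2.81e-11, adjusted p = 0.0421 with an estimated correlation). So were 10 of 16 luminal markers, with 2 lower (median 1.66, camera adjusted p = 2.93e-05, adjusted p = 0.442 with an estimated correlation). Prlr was 214 ± 10.2 in basal and 5550 in luminal cells (limma adjusted p = 1.12e-07). The transporter gene Slco4a1 (16100 to 182, adjusted p = 1.27e-07) and the collagen gene Col6a3 (295 to 24600, adjusted p = 9.36e-07) showed the largest difference in either direction among the genes the naming rule took. Fibroblast markers were higher in luminal cells in 10 of 11 cases (median 3.02, camera adjusted p = 4.7e-06, adjusted p = 0.598 with an estimated correlation). So were 3 of 6 seminal vesicle and urothelial markers (median 2.62, camera adjusted p = 0.00679, adjusted p = 0.598 with an estimated correlation). Their median was 2.15 and 4.89 without CD1 luminal replicate 1 or 2. Without CD1 luminal replicate 2 the calls numbered 2104 and 2598.

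After Pten deletion the lineages still differed at 2027 genes higher in luminal and 2433 higher in basal cells (limma), 45.4% of the calls being higher in luminal cells, or 27.9% with the values as deposited. Basal markers were lower in luminal cells in 17 of 18 cases, with a median of -1.83 (camera adjusted p = 1.52e-13, adjusted p = 0.206 with an estimated correlation). Of 13 secretion genes 12 were higher in luminal cells, with a median of 2.75 (camera adjusted p = 4.87e-11, adjusted p = 0.0453 with an estimated correlation). Of the interferon-stimulated genes 25 of 30 were higher in luminal cells (26 adjusted over the list alone), with a median of 2.24 (camera adjusted p = 1.82e-16, adjusted p = 0.206 with an estimated correlation) and Oas2 at 342 ± 78.1 against 5.05. In CD1 mice 13 of the 30 were higher and 3 lower, with a median of 0.73 (camera adjusted p = 0.0189, adjusted p = 0.668 with an estimated correlation). Also higher in luminal cells after deletion were 12 of 13 mitochondrially encoded genes (13 adjusted over the list alone), with a median of 1 (camera adjusted p = 9.11e-09, adjusted p = 0.21 with an estimated correlation). So were 7 of 10 endothelial markers (8 adjusted over the list alone), with a median of 1.79 (camera adjusted p = 0.000121, adjusted p = 0.38 with an estimated correlation). Of the genes the naming rule took, Clca1 was at 0 in Pten-deleted basal cells and at least 354-fold higher in luminal cells (limma adjusted p = 0.00551), and Tmem132b was higher in basal cells (1790 against 117, adjusted p = 4.06e-05). The calls fell to 611 and 623 without Pten-deleted basal replicate 1, and to 686 and 701 without Pten-deleted basal replicate 2.

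The test of the difference between the 2 Pten effects asked which genes responded otherwise in luminal than in basal cells. It called 798 genes as more positive in luminal cells and 460 as more negative (limma), 63.4% of the calls being positive, or 45.4% with the values as deposited. Basal markers responded more positively in luminal cells at 14 of 18 genes (16 adjusted over the list alone; median 1.97, camera adjusted p = 1.76e-14, adjusted p = 0.23 with an estimated correlation). Secretion genes responded more negatively at 7 of 13 (9 adjusted over the list alone; median -2.01, camera adjusted p = 1.3e-07, adjusted p = 0.0902 with an estimated correlation). The effect on NF-kB target genes was more positive in luminal cells at 10 of 25 genes and more negative at 1 (13 and 1 adjusted over the list alone; median 1.23, camera adjusted p = 1.9e-07, adjusted p = 0.301 with an estimated correlation). For interferon-stimulated genes it was so at 7 of 30 (10 adjusted over the list alone; median 1.32, camera adjusted p = 5.48e-07, adjusted p = 0.301 with an estimated correlation), a median that was 0.79 without Pten-deleted luminal replicate 2. Endothelial markers, at 4 of 10 genes (6 adjusted over the list alone; median 2.39, camera adjusted p = 1.21e-05, adjusted p = 0.301 with an estimated correlation), and smooth muscle markers, at 3 of 9 (8 adjusted over the list alone; median 1.87, camera adjusted p = 1.21e-05, adjusted p = 0.301 with an estimated correlation), also responded more positively in luminal cells. Leukocyte markers did not pass as a group (median -0.36, camera adjusted p = 0.628), and fibroblast markers passed as more negative, at -1.78 (camera adjusted p = 1.48e-06, adjusted p = 0.301 with an estimated correlation). Selp (difference 6.17, limma adjusted p = 0.00841), Egln3, an oxygen-sensing prolyl hydroxylase (5.49, adjusted p = 0.0111), and Stc1 (5.19, adjusted p = 0.00504) had the largest positive differences among the genes the naming rule took. Pnliprp1 (-4.04, adjusted p = 0.00137), Col6a3 (-3.95, adjusted p = 0.00344) and Glb1l3 (-3.86, adjusted p = 8.41e-05) had the largest negative ones. With 1 library left out at a time the differences ranged from 4.77 to 7.57 for Selp, whose call was lost without CD1 luminal replicate 2. They ranged from 4.34 to 6.63 for Egln3, whose call was lost without CD1 luminal replicate 2 or either CD1 basal library. The positive and negative calls numbered 186 and 107 without Pten-deleted basal replicate 1, 201 and 107 without Pten-deleted basal replicate 2, 344 and 160 without CD1 basal replicate 1, and 355 and 309 without CD1 basal replicate 2. They were 1326 and 1044 without Pten-deleted luminal replicate 1, 947 negative without Pten-deleted luminal replicate 2, 470 and 237 without CD1 luminal replicate 1, and 209 and 88 without CD1 luminal replicate 2.

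The genes that changed in both cell types were then counted, in comparisons that share no library but share 1 estimate of the spread per gene. A gene with a small spread passes more easily in both. The counts for independent lists and the Fisher p-values are therefore not exact references. Of the genes called in both, 30 rose in both, where independent lists would share 9.14 (Fisher's exact test, two-sided p = 2.04e-09, adjusted over 4 tests 4.08e-09). Another 30 rose in basal and fell in luminal cells, where independent lists would share 5.46 (Fisher's exact p = 4.63e-15, adjusted 1.85e-14). The genes risen in both included Lyz2, Mmp12, Lilrb4a, Cd74, H2-Aa, Il1b and Laptm5, and those with opposite changes Tgm4 and Glb1l3. Fallen in both were 2 genes against 0.6 (Fisher's exact p = 0.118, adjusted 0.157). Only 1 fell in basal and rose in luminal cells, against 1 (Fisher's exact p = 1). Across all genes, which are not independent replicates, the effects were almost uncorrelated (Pearson r = 0.08, Spearman rho = -0.02). The 32 genes called the same way in both became 3, 4, 3 and 3 without Pten-deleted basal replicate 1 or 2 or CD1 basal replicate 1 or 2. They became 61 and 53 without Pten-deleted luminal replicate 1 or 2, and 13 and 12 without CD1 luminal replicate 1 or 2.

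Lastly, the basal effect was set against the lineage difference, both being measured against the CD1 basal libraries. Of the 91 genes that rose in Pten-deleted basal cells, 65 were higher in CD1 luminal than in CD1 basal cells, where independent lists would share 15.1 (Fisher's exact test, two-sided p = 5.59e-31). Another 4 were higher in basal cells, against 17.4 (exact p = 7.69e-05). Of the 10 that fell, 9 were higher in CD1 basal cells against 1.91 (Fisher's exact p = 2.84e-06), Spry4, Socs2 and Cish being examples. No value with shared controls was simulated for these 9 or for the 4, and sharing the CD1 basal libraries moves both counts in the direction seen. In 20 simulations that placed the called Pten effects on random genes of like basal level and kept the shared controls, 25.2 genes rose on average. Of these 32.4% (15.4% to 44.4%) were higher in CD1 luminal cells, beside 71.4% of the 91 observed. The luminal side of this reference also held fibroblast markers, of which 10 of 11 were higher in CD1 luminal cells (median 3.02), and all 11 lay higher in Pten-deleted basal cells (median 1.39). Across genes the Pearson correlation was 0.41 and Spearman's rho 0.41. Separate simulations, with all 8 libraries drawn at the CD1 basal level, gave means of 0.46 and 0.44 from the shared libraries alone. They held no lineage difference between the cell types, so these correlations are no reference for the observed ones, and only the covariances were compared. The covariance was 0.26 against a simulated 0.098 (0.094 to 0.101), a difference of 0.161. Using a different CD1 basal library for each side, so that none was shared, gave covariances of 0.211 and 0.121. Noise of a shared control library cannot account for these positive values, although each rests on 1 control library per side. A deviation common to both CD1 basal libraries would still enter both sides. The 74 called lineage genes that changed in the direction of the CD1 luminal libraries became 12, 10, 13 and 7 without Pten-deleted basal replicate 1 or 2 or CD1 basal replicate 1 or 2, and 133 and 127 without Pten-deleted luminal replicate 1 or 2.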

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

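All tests of an explanation in this part were chosen after the result was seen. Of the 88 genes named in the text, 57 had a Pten effect that differed between luminal and basal cells (limma interaction, adjusted p from 8.41e-05 to 0.0488), 38 more positive and 19 more negative in luminal cells. Over all genes this test called 1258 of 20733. Many of the 88 were named for a large effect or difference in these same data, so their higher share follows in part from that choice. With 1 library left out at a time 25 of the 57 kept this call throughout and 32 lost it at least once, 25 of them without CD1 luminal replicate 2, and none changed direction. Fewer than 5 of the 8 such fits called Cdh5, Tnip3, Vwf, Wfdc2, Oas2, Krt15, Tacstd2, Snai2, Thbs1, Trp63, Ccnd1, H2-D1, Glb1, Nkx3-1, Lyz2, Fbln1, Cercam and Ms4a5. The differences below are log2 fold change in luminal minus that in basal cells. Luminal-restricted genes lay at 200 or more in CD1 luminal cells and by log2 3 or more above the basal libraries they were chosen on. Basal-restricted genes were called at least log2 3 lower in CD1 luminal than in CD1 basal cells and reached 2000 in Pten-deleted basal cells.

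Among epithelial lineage genes the differences were Krt17 3.8, Wfdc2 3.77, Krt5 3.08, Krt15 2.78, Col17a1 2.61, Tacstd2 2.5, Snai2 2.11, Trp63 1.78, Prlr -1.78, Prom1 -1.83, Nkx3-1 -1.98, Pbsn -2.49, Tgm4 -3.06, Dpp4 -3.09 and Spdef -3.44. Immune genes gave Lcn2 4.67, Tnip3 4.44, Ifit3 3.84, Oas2 3.37, H2-K1 1.43, H2-D1 1.23 and Lyz2 -2.11, and markers of vessels, muscle and stroma Selp 6.17, Cdh5 4.57, Vwf 4.38, Myh11 3.07, Acta2 2.72 and Fbln1 -2.32. Genes of metabolism, growth and signalling gave Egln3 5.49, Stc1 5.19, Ets1 3.65, Mcm3 3.57, Slco4a1 3.55, Pdk4 3.51, Elovl6 2.85, Pfkfb3 2.57, Spry4 2.41, Hmgcs1 2.16, Thbs1 1.87, Ccnd1 1.77, Cish 1.65, Socs2 1.58, Cdkn1a 1.44, Glb1 -1.77 and Igfbp5 -2.58. The remaining differences were Gm26870 6.68, Gm21738 6.33, Gm10801 5.62, Gm10800 4.53, Cercam -2.44, Ms4a5 -2.83, Gucy2g -3.64, 9530053A07Rik -3.7, Ren1 -3.85, Glb1l3 -3.86, Col6a3 -3.95 and Pnliprp1 -4.04. For the Gm genes a source in the make-up of the Pten-deleted luminal libraries was not tested.

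Luminal genes were higher in Pten-deleted than in CD1 basal cells. A fall in CD1 basal replicate 1 alone was argued against, because 96.6% of 355 luminal-restricted genes chosen on that library lay above replicate 2, as did 94.3% of 159 chosen on the Pten-deleted basal mean, where 1 replicate lay above the other of its group at 47.7% to 57.9% of such genes. Luminal cells or their RNA in the Pten-deleted basal sort may account for part of it, as 93.1% of 350 genes chosen on CD1 basal replicate 2 lay above replicate 1, by a median of 5.51% of their luminal level (0.988% and 14.8% at the 10th and 90th percentiles), although those genes include 6 fibroblast markers that the CD1 luminal libraries also held. The 65 genes that rose and were higher in CD1 luminal cells gained a median of 9.46% (3.81% to 101%), among them Pnliprp1 (52.1%), Ms4a5 (35.1%) and Ren1 (21.9%). They were chosen for their rise over the same CD1 basal libraries, so a gain above 5.51% is in part built in. Of the abundant secretion genes, Tgm4 (6.8%) and Pbsn (4.65%) lay near the 5.51%, and Sbp (2.14%) and Spink1 (0.797%) gained less. A start of luminal expression in basal cells, which the design names as a question, stays open and was not tested, since the sort gates and single cells were not analysed here.

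Leukocyte genes were higher in the same Pten-deleted basal cells. All 14 markers lay higher, Ptprc at 60.1 against 2.89 among them. Leukocytes carried through the sort cannot be told apart from expression in basal cells, since 5 of 7 MHC class II genes, none of them among these markers, lay higher and H2-DMa and Ciita did not (log2 -0.32 and -0.02). A loss of purity for every other cell type alike stays open as well, since the leukocyte median lay above the endothelial and smooth muscle medians by 1.48 with all libraries but by 0.51 without CD1 basal replicate 2, where the SD over left-out libraries was 0.33, and above the fibroblast median of 1.39 by only 0.26 (-0.24 to 0.5 over left-out libraries). A larger number of leukocytes in the tissue after deletion stays open as a biological difference and was not tested.

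Basal genes were higher in Pten-deleted luminal cells. The lower depth of these libraries was argued against, because 14 of 18 basal markers still rose with every library thinned to 1276100 reads. Basal cells carried over at one share cannot be told apart from expression in luminal cells. The share of the basal level gained varied 4.64-fold between the 10th and 90th percentiles of 147 basal-restricted genes (7.54% and 35%). Differences between the Pten-deleted luminal libraries alone would give 2.15-fold, and the 95% bootstrap interval of 3.72 to 6.28 lies above that. The interval spans 4.3, a wider margin for excluding a single share that was set after the result was seen. The 2.15 leaves out noise in the basal and CD1 luminal levels, so the excess over it does not settle the question. Krt5 gained 13.5%, Trp63 6.8%, Krt17 25.3% and Krt15 26.7%, and luminal cells derived from labelled basal cells stay open too, since the labels used here do not say whether the YFP reporter entered the luminal sort. A loss of purity for several other cell types in this sort stays open as well and was not tested. Endothelial, smooth muscle and leukocyte markers also lay higher there, with median log2 fold changes of 2.31, 1.31 and 1.3 beside 1.85 for basal markers. The fibroblast median was -0.41.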

How the results depend on the processing

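Thinning, library weights and leaving out both libraries that stood apart were tests chosen after the results were seen, and the others were planned. Over the alternatives no named gene changed direction while called. The cause of each shift below was not tested unless stated. In Pten-deleted luminal replicate 1, 1 read is worth 15.67 normalised reads, which limits what can be seen of weakly expressed genes there.

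The basal Pten count (91 higher, 10 lower) became 40 and 3 with a pseudocount of 1, 11 and 0 without a filter, and 11 and 0 without a variance trend. It became 249 and 54 with edgeR (17.7% false calls in simulated data), 280 and 69 with DESeq2, 52 and 3 with only the 4 basal libraries, 27 and 2 after thinning, 331 and 90 with library weights, and 17 and 1 without both libraries that stood apart. Its lower calls were 5 with the values as deposited and 16 with a filter of 100. All 101 basal calls were also called by edgeR. The luminal Pten count (2082 and 1245) became 3 and 0 with only the 4 luminal libraries, 1099 and 262 after thinning, and 1335 and 484 with library weights. Its lower calls were 756 with edgeR, 642 with DESeq2 and 2609 without both libraries, and 2170 of the 3327 calls were shared with edgeR. The lineage count after deletion (2027 and 2433) became 1142 and 1045 after thinning, and its lower calls 3766 as deposited, 1620 with edgeR and 1527 with DESeq2. The difference between the Pten effects (798 and 460) became 494 higher as deposited, 243 and 141 without a filter, 180 and 165 without a trend, 334 and 152 after thinning, and 1425 and 1127 without both libraries.

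Values as deposited shifted the median of all genes by 0.06 in basal and -0.09 in luminal cells, by -0.08 and -0.23 for the lineage differences before and after deletion, and by -0.15 for the difference between effects, so directions there are relative to the median-ratio scaling.

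The genes called the same way in both cell types (32) became 8 with a pseudocount of 1, 4 without a filter, 5 after thinning and 4 without both libraries. Their correlation (0.08) was 0.12 and 0.02 with pseudocounts of 1 and 40, 0.04 with a filter of 100, 0.05 after thinning and 0.04 without both libraries. The lineage genes that changed in the direction of CD1 luminal cells (74) became 39 with a pseudocount of 1, 10 without a filter, 25 after thinning and 17 without both libraries. Their correlation (0.41) was 0.37 after quantile normalization and 0.46 with a filter of 100, and the covariance (0.26) was 0.433 and 0.16 with pseudocounts of 1 and 40, 0.171 without a filter and 0.412 after thinning.

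Leaving out 1 library at a time gave, for higher and lower calls, 7 to 158 and 0 to 25 in basal cells, 773 to 2268 and 165 to 1878 in luminal cells, 2104 to 4296 and 2598 to 4972 for the CD1 lineages, 611 to 2091 and 623 to 3141 for the lineages after deletion, and 186 to 1326 and 88 to 1044 for the difference. The genes called the same way ranged from 3 to 61 with correlations of 0.05 to 0.11, and the lineage genes from 7 to 133 with correlations of 0.39 to 0.51 and covariances of 0.252 to 0.419. Beside the 0 lower calls in basal cells, 145 to 719 genes were lower at an unadjusted p under 0.05 without a basal library. The endothelial median in basal cells (0.17) was -0.51 without CD1 basal replicate 1, 0.75 without CD1 basal replicate 2 and -0.52 without both libraries, and the immediate early median (-0.06) was -0.42 without CD1 basal replicate 1 and 0.33 without CD1 basal replicate 2. Of 536 list calls 487 were kept and 49 lost, and 22 of 424 list results without a call gained one. Of 3026 gene calls 2451 were kept and 575 lost, and 20 of 702 gene results without a call gained one.

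With an estimated correlation 63 of 67 list calls were lost. camera passed 10 of 24 lists in basal and 15 in luminal cells, 2 and 0 with an estimated correlation, and fry 3 and 18. Pairing of the samples by replicate number was not shown (correlations of deviations between -0.068 and 0.197, the highest being that of CD1 basal with CD1 luminal cells). With 1 replicate difference per group, such correlations cannot exclude it. A replicate block gave 121 and 11 genes in basal cells, 2163 and 1302 in luminal cells and 916 and 517 for the difference, and kept 380 of 381 gene calls and 64 of 67 list calls, with 4 genes and 3 lists gaining one.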

Other observations

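The genes in this part were chosen after their values were seen. Igfbp5, which binds insulin-like growth factors, was among the most abundant genes to rise in Pten-deleted basal cells, at 46900 ± 98.3 against 6690 ± 990 (log2 2.81, SE 0.32, limma adjusted p = 0.00541), with 9120 ± 824 and 8490 ± 4890 in luminal cells. Its call was lost without CD1 basal replicate 1 or 2, with log2 values between 2.66 and 2.96. The alarmin gene Il33 rose in both cell types (log2 1.66, adjusted p = 0.0227 in basal and 1.58, adjusted p = 0.00321 in luminal cells). So did the carbonic anhydrase gene Car12 (2.22, adjusted p = 0.00541 and 3.14, adjusted p = 0.000106) and the heme oxygenase gene Hmox1 (1.49, adjusted p = 0.0314 and 1.6, adjusted p = 0.00248). In luminal cells these 3 kept their call without each library. In basal cells they lost it without any 1 of the 4 basal libraries, and Il33 also without CD1 luminal replicate 2. Their values there lay between 1.29 and 2.03, 1.94 and 2.48, and 1.41 and 1.56. Ets1, a transcription factor gene, rose from 259 ± 33.7 to 3440 ± 236 in luminal cells (log2 3.69, adjusted p = 5.91e-06), beside 6820 ± 209 in Pten-deleted and 6670 ± 359 in CD1 basal cells. Thbs1, encoding thrombospondin 1, rose from 13400 ± 2780 to 71600 ± 26300 (2.39, adjusted p = 0.000801). Both kept this call without each library, but the larger effect on Thbs1 in luminal than in basal cells (difference 1.87, interaction adjusted p = 0.0254) passed in 2 of 8 fits with 1 library left out, at 1.47 to 2.25, and was lost without any 1 basal or CD1 luminal library.

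A set of predicted genes was measured higher in Pten-deleted luminal cells alongside the share of ribosomal RNA loci. Those libraries had the fewest reads (1276100 and 1707022), and loci of 18S and 45S ribosomal RNA took 22.22% and 15.34% of them. Whether the rise came from the cells or from the make-up of these libraries was not tested. Gm10800 was at 62200 ± 16600 against 971 ± 799 in CD1 luminal cells (log2 6.25, SE 0.52, limma adjusted p = 0.000122) and 429 ± 168 in Pten-deleted basal cells. Gm10801 (11100 ± 2270 against 104 ± 70), Gm21738 (11100 ± 4510 against 139 ± 41.7) and Gm26870 (4870 ± 379 against 66.6 ± 4.69) rose by log2 6.74, 6.19 and 5.99, and the 4 kept their call without each library. The gene 9530053A07Rik took 6.28% and 9.35% of the reads in CD1 luminal cells, 2.92% and 2.38% in Pten-deleted luminal cells, 1.11% and 1.17% in Pten-deleted basal cells and 0.19% and 0.27% in CD1 basal cells.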
